A study of Homo sapiens with 6 samples.

How the data were processed

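Bulk messenger RNA was measured in 6 libraries of F36P cells, 3 transduced with a guide RNA against HDAC7 (sgHDAC7) and 3 with a non-targeting guide (sgNT). Per the labels' protocols, total RNA was extracted from each library's cells, messenger RNA was captured on poly-T beads, and the fragmented RNA was copied with random hexamers. The authors deposited 1 table of all 6 libraries. Its name calls the values CPM, but the deposited values are whole-number read counts per gene: 100% of them are whole, and the column totals differ between libraries. They were therefore treated as unscaled counts. Per the submitters' processing notes, genome build hg38 and edgeR 3.32.1 were used, without a stated role. The aligner, the counting tool, the annotation and the use of strand are not given in the sources used here. Each of the 16315 genes in the table exceeds 0.5 CPM in at least 2 libraries, so genes below that level are not analysed here. The table has no row without a gene name and 0 further columns of values. Columns were matched to samples by the HDAC7 name and number. The columns named NC were taken as the sgNT libraries, because they are the only columns without HDAC7 in their name and sgNT is the only other group.

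Library totals ran from 10039693 to 12521195 counts. At that depth, 3 counts in a library correspond to 0.24 to 0.299 CPM, which covers counting error only.

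The design fixed before the data were examined assumed CPM values and named limma-trend on log2(CPM + 0.5) as the test. Because the file holds counts, the test used was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling and group as the single term. It ran on 13841 genes with a mean CPM of at least 1 over the 6 libraries. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values in the text are TMM-scaled and given as mean ± SD of 3 libraries. Errors of log2 fold changes are standard errors, taken as the log2 fold change over the square root of the edgeR F statistic. The planned limma test (limma 3.58.1) and DESeq2 1.42.0 were run as alternatives. Positions of genes come from GENCODE 29 on GRCh38.

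Gene lists (32, all fixed before the data were examined) were tested with camera from limma on log2(CPM + 0.5), with a preset inter-gene correlation of 0.01. They cover erythroid genes, other blood lineages, the cell cycle, stress responses and RNA quality. Names of the mitochondrially encoded genes were matched to the spelling of the table after it was seen. Beside camera stand camera with an estimated correlation, and fry. The genes named are HDAC7 and the other classical histone deacetylases, a fixed panel of 17 erythroid and progenitor genes, the 10 largest rises and 10 largest falls, and up to 4 members per list. The largest rises and falls were taken among genes with an adjusted p under the threshold, a mean CPM of at least 5 and groups that do not overlap. List members were those with the smallest adjusted p under the threshold. Any other gene is said to be chosen after its values were seen. Some genes that meet these rules are not used here.

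Replicate 1 of both groups stood apart from replicates 2 and 3. A fit with a term for replicate 1, and a fit on replicates 2 and 3 alone, were therefore added after seeing the data. Their values stand beside the pooled ones. Other alternatives, planned beforehand, were the pseudocount, the filter on low values, the scaling, the variance model, the replicate number as a block and leaving out each library. The pseudocount, quantile and variance alternatives were run in the limma fit, and for lists the robust prior was run through camera on ranked gene statistics.

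The scripts were tested on simulated counts for the same 13841 genes, in 3 runs with 200 changed genes each. The genes of a planted list were raised in the same counts in addition, and their calls were not counted as false. edgeR recovered 50.3% of the genes changed 1.5-fold and 78.7% of those changed 2-fold for the sgHDAC7 against sgNT comparison, and 7.38% of its calls were false. With the replicate 1 term, on counts with a simulated replicate 1 shift, it recovered 47.7% and 75.3%, with 10.3% false calls. The simulated shift was the same for both guides. These rates therefore do not cover genes whose guide difference varies between replicate 1 and the other replicates. DESeq2 recovered 57% and 81%, with 11.9% false calls, and limma 48.3% and 79.3%, with 7.26%. The simulated genes varied independently. The planted list was called in 3 of 3 runs by camera, by camera with an estimated correlation and by fry, and of 60 unchanged lists these called 0, 0 and 1.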

Results

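RNA-seq was carried out in F36P, a cytokine-dependent human leukaemia line with erythroid features. The cells carried a CRISPR guide RNA against HDAC7, a class IIa histone deacetylase, or a non-targeting guide, and were sequenced after selection in 1 µg/ml puromycin for 4 days. Each group held 3 libraries, labelled as biological replicates. The sgHDAC7 libraries had 12468419, 11645003 and 12521195 counts, and the sgNT libraries 10039693, 11149179 and 10443774. Mitochondrially encoded messenger RNAs took 3.46% to 3.79% of counts in sgHDAC7 and 2.72% to 3.96% in sgNT, with the lowest share in sgNT replicate 3. The series asks how HDAC7 bears on the erythroid state of these cells, and sgHDAC7 against sgNT is its only comparison.

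The targeted gene was checked first. HDAC7 (12:47782722-47833132, minus strand, GRCh38) had 226 ± 28.0 CPM in sgHDAC7 (n = 3) and 457 ± 6.51 CPM in sgNT (n = 3), a level of 49.5% of the control. The single libraries ran from 194.2 to 246 CPM in sgHDAC7 and from 449.9 to 461.8 CPM in sgNT, so all 3 sgHDAC7 libraries lay below all 3 controls. The edgeR log2 fold change was -1.02 ± 0.09 (adjusted p = 0.00139). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. HDAC7 protein and editing are not part of these data, so the 49.5% describes messenger RNA alone. HDAC5 (17:44076746-44123702, minus strand), another class IIa deacetylase, rose 4.37-fold, from 13.3 ± 1.42 to 58.2 ± 7.27 CPM (log2 2.13 ± 0.13, edgeR adjusted p = 0.000265). It was higher in all 3 sgHDAC7 libraries. HDAC1, HDAC2, HDAC3, HDAC4, HDAC6, HDAC8, HDAC10 and HDAC11 had log2 fold changes between -0.23 and 0.19, and none passed the edgeR test. HDAC9 is not analysed here.

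**Figure D1:**
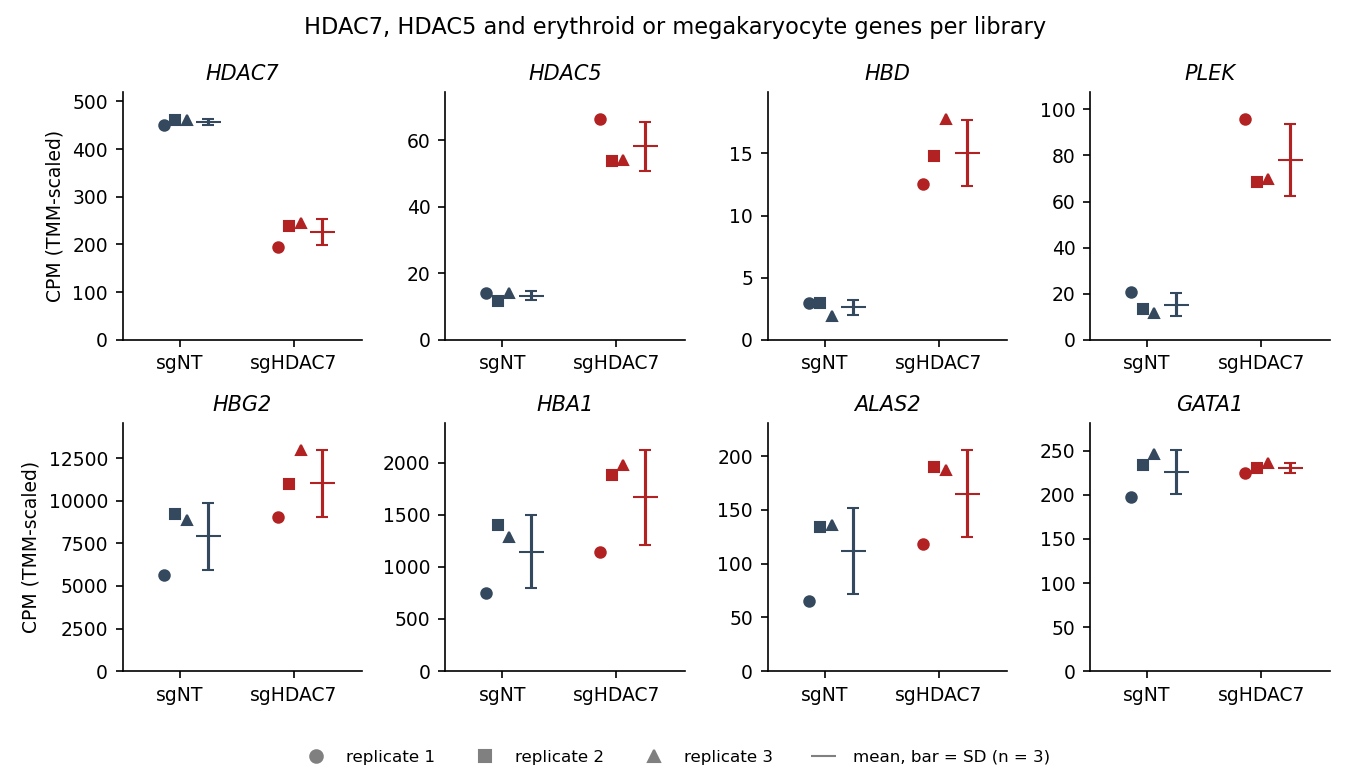
Scaled CPM (vertical axes, linear and starting at 0) of 8 genes in the 3 sgNT and 3 sgHDAC7 libraries, with a symbol per replicate and the mean ± SD beside them. HDAC7 lies between 194.2 and 246 CPM in sgHDAC7, below the 449.9 to 461.8 CPM of sgNT, and in HBG2, HBA1 and ALAS2 replicate 1 is the lowest library of both groups.

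At the level of the transcriptome, 396 of 13841 tested genes changed, 161 higher and 235 lower in sgHDAC7 (edgeR adjusted p under 0.05). At least 2-fold changes were found for 22 higher and 57 lower genes. In 3480 genes (25.1%) the groups did not overlap, against 10% by chance. The first principal component (34.7% of the variance) separated sgHDAC7 from sgNT, and the second (31.4%) separated replicate 1 of both groups from replicates 2 and 3. A term for replicate 1 raised the edgeR count to 1743 genes (800 higher, 943 lower), among them all 396. On replicates 2 and 3 alone (2 against 2) it called 2847. The replicate 1 term assumes the same difference between the guides in replicate 1 as in replicates 2 and 3. For the ATF4 list, described below, the median log2 ratio was -0.20 in replicate 1 and -1.03 in replicates 2 and 3. Haem synthesis genes stood at 0.31 and -0.06, and mast cell genes at 0.02 and -0.58. Cholesterol synthesis genes were closer, at -0.34 and -0.24. By effect size, the assumption thus held unevenly across lists. With 1 replicate 1 library per group, a test of it has no spread between replicate 1 cultures. With group alone, the count was 1588 without sgNT replicate 1 and 228 without sgHDAC7 replicate 1. It fell to 27 and 31 without sgHDAC7 replicate 2 or 3, and to 47 and 50 without sgNT replicate 2 or 3. All 396 kept their sign in each of these fits and between the 2 replicate 1 libraries alone. The 396 were chosen on these same libraries, so the kept signs are no independent support. Replicates 2 and 3 of each group lay close together (chi-square per degree of freedom 3.20 and 3.50, against 7.74 to 15.4 for pairs with replicate 1). The labels call them biological replicates without saying whether they were grown apart. If they were not, the counts of 1743 and 2847 rest on too small a spread. The 396, the counts without single libraries and the p-values of the list tests would then be affected too.

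**Figure D2:**
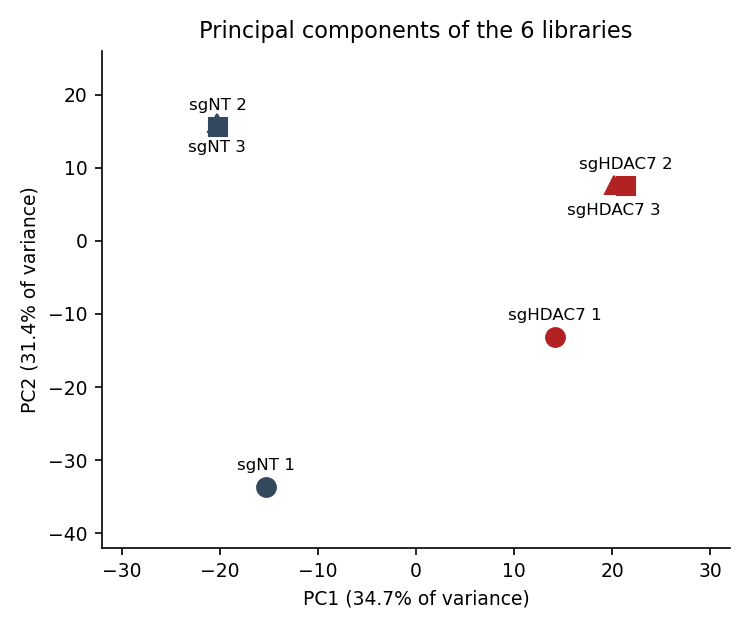
Principal components 1 and 2 of the log2 CPM of the 6 libraries (axes in component units, with the share of variance), coloured by guide and with a symbol per replicate. Replicates 2 and 3 of each guide lie almost on top of each other, and replicate 1 lies apart from them along PC2, at -13.15 for sgHDAC7 and -33.65 for sgNT.

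The 10 largest rises included a haemoglobin chain, a platelet protein and cytoskeletal genes. HBD, the delta chain of haemoglobin A2, rose 5.74-fold from 2.61 ± 0.62 to 15.04 ± 2.63 CPM (edgeR adjusted p = 0.00139). PLEK, which encodes the platelet protein pleckstrin, rose 5.12-fold and EXOC3L4 5.02-fold. HDAC5 was followed by MYO18B (2.64-fold), HSPA1B and HSPA1A (2.57-fold and 2.54-fold), TRIB1 (2.42-fold) and ADD2 (2.33-fold). HSPA1A and HSPA1B are near-identical copies, so the split of reads between them is uncertain. HBD, PLEK, EXOC3L4 and HDAC5 passed the edgeR test whichever library was left out. The HSP70 genes, MYO18B and TRIB1 did not pass without sgHDAC7 replicate 2 or 3 or sgNT replicate 2 or 3. Among the single-library omissions, ADD2 kept its call only without sgNT replicate 1.

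The 10 largest falls were led by CHAC1, a glutathione-degrading enzyme, with 3.38 ± 0.40 CPM in sgHDAC7 and 46.1 ± 33.0 CPM in sgNT (13.6-fold lower, edgeR adjusted p = 0.0249). DDIT4, an inhibitor of mTORC1 signalling, was 9.13-fold lower. VLDLR, ATF3, SESN2, SLC7A11, CTH, JDP2, PSAT1 and TRIB3 were 3.50-fold to 6.91-fold lower. They include the cystine transporter SLC7A11, the transsulfuration enzyme CTH and the serine synthesis enzyme PSAT1. The high sgNT values were those of replicates 2 and 3. DDIT4 stood at 802 and 812 CPM there and at 104 CPM in sgNT replicate 1, against 57.3 to 66.2 CPM in sgHDAC7. Between the 2 replicate 1 libraries the log2 ratios of the 10 genes ran from -0.99 (CHAC1) to -0.17 (TRIB3). When single libraries were left out, SLC7A11 kept its call only without sgHDAC7 replicate 1 or sgNT replicate 1. The other 9 kept theirs only without sgNT replicate 1.

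**Figure D3:**
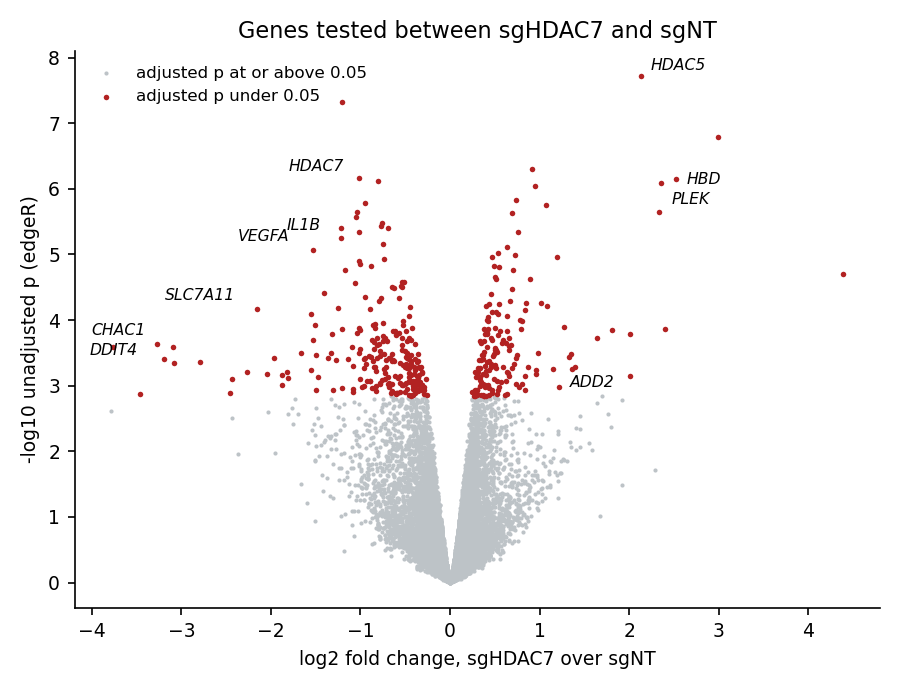
Log2 fold change of sgHDAC7 over sgNT (horizontal) against -log10 of the unadjusted edgeR p (vertical) for the 13841 tested genes, with the 396 called genes in red. HDAC5 lies at the upper right, HDAC7 at the upper left, and CHAC1 and DDIT4 at the far left with moderate p-values.

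Among erythroid genes, the haemoglobin list was higher in sgHDAC7 (10 measured members, median log2 fold change 0.39, camera adjusted p = 0.0232; adjusted p = 0.611 with an estimated correlation). HBD alone passed the edgeR test among all genes tested, and also adjusted over the list alone. HBG2, a fetal gamma chain, had 11023 ± 1966 CPM in sgHDAC7 and 7916 ± 1965 CPM in sgNT. HBA1, an alpha chain, had 1668 ± 456 and 1146 ± 348 CPM, and neither passed with group alone (edgeR adjusted p = 0.188 and 0.264). With the replicate 1 term, HBD, HBG2, HBA1 and HBA2 were higher (HBA2 chosen after its values were seen), HBG2 by log2 0.50 (edgeR adjusted p = 0.000993) and HBA1 by 0.55 (7.65e-05). HBG1, the other gamma gene, had a log2 fold change of 0.15 ± 0.20 (edgeR adjusted p = 0.741). Reads of HBG1 and HBG2, and of HBA1 and HBA2, may have been split between these near-identical copies. The haemoglobin list was not called without sgHDAC7 replicate 3 or without sgNT replicate 1 (camera adjusted p up to 0.381).

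The red cell membrane list was also higher (25 members, median 0.12, camera adjusted p = 0.00682; adjusted p = 0.726 with an estimated correlation). SPTB, the beta chain of spectrin, rose 1.75-fold and ADD2, beta adducin, 2.33-fold, 2 genes over all genes tested and 4 adjusted over the list alone. In the fit with the replicate 1 term 11 members were higher. The iron list was higher as well (15 members, median 0.12, camera adjusted p = 0.00919; adjusted p = 0.497 with an estimated correlation). FTL, the ferritin light chain, rose from 1942 ± 209 to 2729 ± 329 CPM (log2 0.49 ± 0.10, edgeR adjusted p = 0.0384). It was the only call in that list, against 3 adjusted over the list alone and 5 with the replicate 1 term. The transferrin receptor TFRC, with 2834 ± 132 and 2459 ± 206 CPM, passed only in the fits with the replicate 1 term or on replicates 2 and 3 (log2 0.21 and 0.17), and its sign turned under quantile normalization. Both lists lost their calls without sgNT replicate 1 (camera adjusted p = 0.266 and 0.138). The medians of the membrane and iron lists were 0.31 and 0.29 between the replicate 1 libraries, and 0.11 and 0.10 between replicates 2 and 3.

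Erythroid transcription factors as a list were not called (19 members, median 0.07, camera adjusted p = 0.28). GATA1, the master erythroid factor, had 231 ± 5.88 CPM in sgHDAC7 and 226 ± 25.04 CPM in sgNT (log2 0.03 ± 0.08, edgeR adjusted p = 0.891). KLF1 and TAL1 had log2 fold changes of 0.12 ± 0.10 and 0.09 ± 0.06. Neither passed with group alone or with the replicate 1 term. ZBTB7A, a repressor of fetal globin genes, was the single call (1.26-fold higher, edgeR adjusted p = 0.0317), against 2 higher and 1 lower adjusted over the list alone. EPOR, the erythropoietin receptor, and ALAS2, the first enzyme of erythroid haem synthesis, had log2 fold changes of 0.26 ± 0.20 and 0.56 ± 0.26 with group alone. Both passed with the replicate 1 term (log2 0.29 and 0.60, edgeR adjusted p = 0.023 and 0.000305). Between the replicate 1 libraries the log2 ratios were 0.57 for EPOR and 0.84 for ALAS2, against 0.16 and 0.48 between replicates 2 and 3. The haem synthesis list (14 members, camera adjusted p = 0.43) and the late erythroid list (20 members, 0.871) were not called. Their medians were 0.31 and 0.17 between the replicate 1 libraries, and -0.06 and -0.08 between replicates 2 and 3. In the late list TRIM58 rose 1.42-fold and BNIP3L, a mitophagy receptor, fell 1.33-fold. The replicate 1 term gave 3 higher haem synthesis genes, 2 higher and 3 lower late genes, and 3 higher and 1 lower transcription factor genes.

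Stem and progenitor genes were lower in sgHDAC7 (9 members, median -0.47, camera adjusted p = 0.00908; adjusted p = 0.434 with an estimated correlation). HHEX fell from 115 ± 9.02 to 69.1 ± 6.17 CPM (log2 -0.73 ± 0.09, edgeR adjusted p = 0.00526), and MSI2 fell 1.39-fold. These were the 2 calls over all genes, and 4 were lower and 1 higher adjusted over the list alone. CD34, KIT and MYB had log2 fold changes of -0.65 ± 0.51, -0.94 ± 0.29 and -0.21 ± 0.10, with edgeR adjusted p = 0.533, 0.113 and 0.286. The replicate 1 term left 5 members lower, CD34 (log2 -0.55) and MYB (-0.21) among them. CD34 was higher in replicate 1 of both groups, at 30.2 CPM in sgHDAC7 and 56.8 CPM in sgNT against at most 16.1 CPM in the other libraries. GATA2 did not differ detectably (632 ± 167 and 634 ± 166 CPM).

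Of 5 lists of other lineages, 2 were called. Monocyte genes were lower (9 members, median -0.18, camera adjusted p = 0.0106; adjusted p = 0.444 with an estimated correlation), with ITGAM, an integrin of myeloid cells, 1.92-fold lower (edgeR adjusted p = 0.0305) as the only call, also adjusted over the list alone. Granulocyte genes were lower as a list (7 members, median -0.23, camera adjusted p = 0.00919; adjusted p = 0.434 with an estimated correlation), although no member passed over all genes and 3 did adjusted over the list alone. SPI1, a member of that list and the myeloid factor PU.1, had a log2 fold change of -0.18 ± 0.09 (edgeR adjusted p = 0.333). Megakaryocyte genes were not called as a list (14 members, camera adjusted p = 0.144), but PLEK and TUBB1, a platelet tubulin, rose 5.12-fold and 1.63-fold. Mast cell and basophil genes (13 members, camera adjusted p = 0.396) and lymphoid genes (7 members, 0.871) held no call. In the fit with the replicate 1 term, 2 monocyte and 3 granulocyte genes were lower, mast cell genes stood at 4 lower and 1 higher, and megakaryocyte genes at 3 higher and 1 lower.

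Genes of the ATF4 and unfolded protein response pathway showed the lowest median of all 32 lists (27 members, median -0.87, camera adjusted p = 1.76e-09; adjusted p = 0.49 with an estimated correlation). Of the 27 members, 14 fell and none rose over all genes tested, against 20 lower and 2 higher adjusted over the list alone. XBP1, a transcription factor of the unfolded protein response, fell from 160 ± 12.05 to 99.4 ± 3.00 CPM (log2 -0.69 ± 0.07, edgeR adjusted p = 0.00275). SLC7A11, SLC7A5, an amino acid transporter, and CHAC1 were 4.45-fold, 1.82-fold and 13.6-fold lower. XBP1 passed whichever library was left out. Among the single-library omissions, SLC7A5 kept its call only without sgNT replicate 1. The list's median log2 ratio was -0.20 between the replicate 1 libraries and -1.03 between replicates 2 and 3, and with the replicate 1 term 20 members were lower and 2 higher. Not every member fell (the following genes were chosen after their values were seen). HSPA5, SDF2L1, HYOU1 and PDIA4 had log2 fold changes of 0.35, 0.34, 0.03 and 5e-04. HSPA5 and ATF5 were the 2 higher with the replicate 1 term. ERN1 and DNAJB9 had -0.29 and -0.20, and neither passed with group alone or with the replicate 1 term. ATF4 itself had -0.53 and did not pass with group alone (edgeR adjusted p = 0.0687). It was lower in each sgHDAC7 library than in each sgNT library, and passed with the replicate 1 term (log2 -0.51, edgeR adjusted p = 0.00334).

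**Figure D4:**
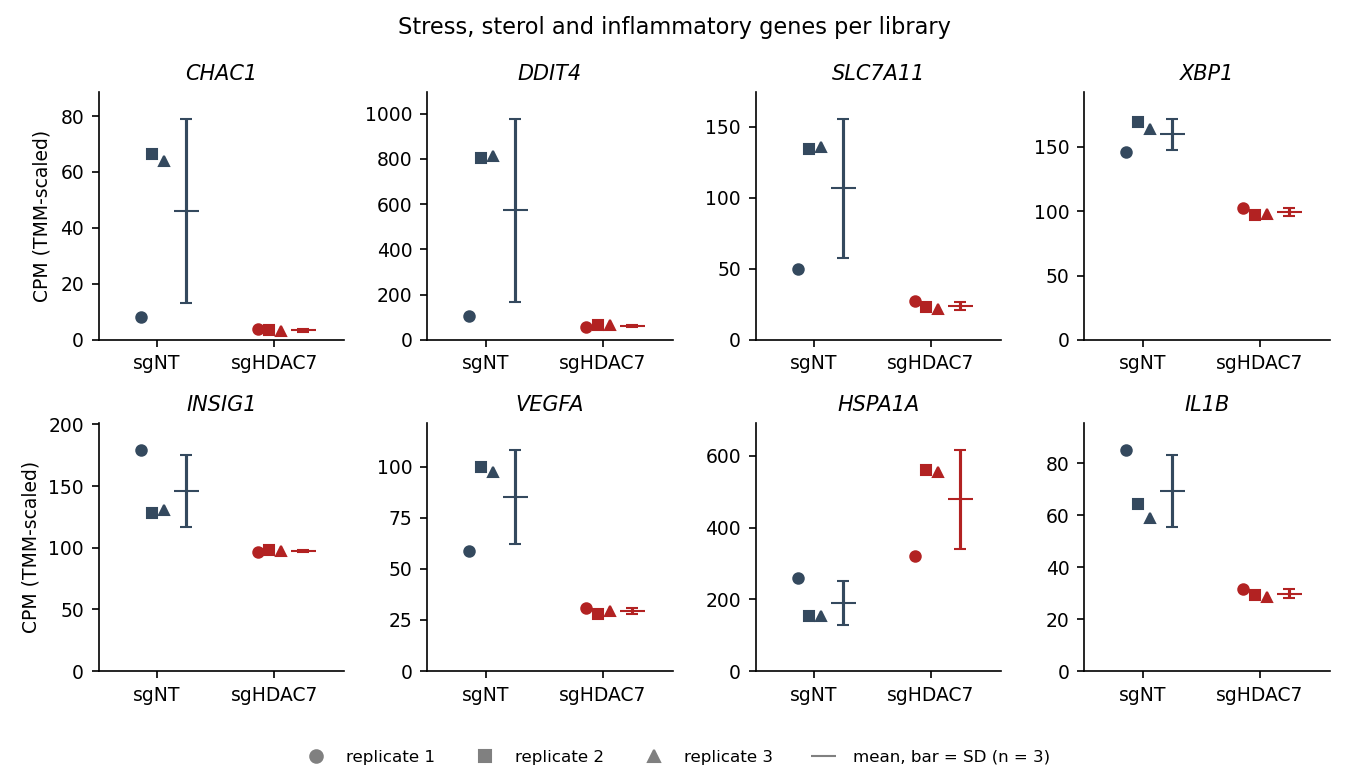
Scaled CPM (vertical axes, linear and starting at 0) of 8 genes in the 3 sgNT and 3 sgHDAC7 libraries, with a symbol per replicate and the mean ± SD beside them. CHAC1, DDIT4, SLC7A11, XBP1, VEGFA and IL1B are lower in each sgHDAC7 library than in each sgNT library, and in CHAC1, DDIT4, SLC7A11 and VEGFA sgNT replicate 1 lies well below sgNT replicates 2 and 3.

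Cholesterol synthesis genes were lower (24 members, median -0.29, camera adjusted p = 1.02e-06; adjusted p = 0.49 with an estimated correlation). FDFT1, which encodes squalene synthase, fell from 293 ± 23.0 to 214 ± 24.1 CPM (log2 -0.46 ± 0.09, edgeR adjusted p = 0.0343). INSIG1 and MVK also fell, with log2 fold changes of -0.58 ± 0.12 and -0.56 ± 0.12, among 5 calls in all against 12 lower and 1 higher adjusted over the list alone. The replicate 1 term gave 13 lower and 2 higher members. The p53 list was lower (21 members, median -0.13, camera adjusted p = 0.0316; adjusted p = 0.434 with an estimated correlation). Its 2 calls were CCNG1, 1.48-fold lower, and SESN2, which is also in the ATF4 list's 14 calls. CDKN1A was below the filter on low values. Cytokine receptor and STAT5 response genes were lower (17 members, median -0.20, camera adjusted p = 0.00497; adjusted p = 0.497 with an estimated correlation), with CSF2RA, the GM-CSF receptor alpha chain, 1.87-fold lower as the only call, 2 adjusted over the list alone and 4 with the replicate 1 term. The STAT5 list's median was -8e-04 between the replicate 1 libraries and -0.26 between replicates 2 and 3. Adjusted over the list alone, the p53 list held 8 lower and 1 higher, and with the replicate 1 term 7 lower and 1 higher.

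Single inflammatory genes changed without a call of their lists. IL1B, the cytokine interleukin 1 beta, fell from 69.5 ± 14.0 to 29.9 ± 1.63 CPM (log2 -1.22 ± 0.14, edgeR adjusted p = 0.00338), and ICAM1 and BCL3 fell 1.73-fold and 1.92-fold. SOD2 in the same list rose 1.27-fold (12 members, camera adjusted p = 0.08; 1 higher and 4 lower adjusted over the list alone). The interferon-induced genes IFITM1, IFITM3 and BST2 fell 1.93-fold, 1.47-fold and 1.30-fold (26 members, camera adjusted p = 0.848; 4 lower adjusted over the list alone). Among immediate early genes ZFP36 rose 1.75-fold, and FOSL2, BTG1 and ATF3 fell (17 members, camera adjusted p = 0.913; the median was 0.16 and the camera direction down). In the glycolysis and hypoxia list, VEGFA was 2.89-fold lower and DDIT4 9.13-fold lower (26 members, camera adjusted p = 0.871). IL1B and IFITM1 passed whichever library was left out, and VEGFA and ICAM1 failed without sgHDAC7 replicate 2 or 3. Higher and lower genes with the replicate 1 term were 1 and 4 in the list of IL1B, 3 and 4 among interferon, 5 and 3 among immediate early, and 1 and 3 among glycolysis genes.

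DNA replication genes were higher (30 members, median 0.14, camera adjusted p = 2.95e-05; adjusted p = 0.604 with an estimated correlation). GINS4, a subunit of the replicative helicase, rose 1.42-fold as the only call (edgeR adjusted p = 0.0317), against 7 adjusted over the list alone and 10 with the replicate 1 term. Ribosome biogenesis genes were higher (28 members, median 0.14, camera adjusted p = 0.00138; adjusted p = 0.604 with an estimated correlation), with UBTF, an RNA polymerase I factor, 1.23-fold higher as the only call. Adjusted over the list alone 4 were higher and 1 lower, and with the replicate 1 term 7 and 1. The list's median was -0.04 between the replicate 1 libraries and 0.21 between replicates 2 and 3. MYC, in the same list, had 725 ± 69.5 CPM in sgHDAC7 and 900 ± 84.1 CPM in sgNT (edgeR adjusted p = 0.102), and passed with the replicate 1 term (log2 -0.31, adjusted p = 0.00185). Ribosomal protein genes were lower as a list (72 members, median -0.11, camera adjusted p = 1.65e-07; adjusted p = 0.604 with an estimated correlation) with no call among members, also adjusted over the list alone, and 12 lower with the replicate 1 term. Histone genes were lower (18 members, median -0.45, camera adjusted p = 0.000231; adjusted p = 0.434 with an estimated correlation). H2BC5, H2BC21, H3C10 and H2BC12 fell 1.52-fold to 1.91-fold, against 6 adjusted over the list alone. Most transcripts of such genes lack a poly(A) tail, and these libraries were selected on poly(A).

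Over all 32 lists, 5 were higher and 9 lower by camera with the preset correlation, and the same numbers were called with the replicate 1 term. None was called with an estimated correlation in either fit (3 lists at an unadjusted p under 0.05 in the fit with group alone), and fry called 3, all lower: stem and progenitor, p53 and histone genes. Among the lists not called, mitotic genes (25 members, camera adjusted p = 0.193) held 1 call, CDC20, 1.22-fold higher. The other histone deacetylases (15 members, 0.335) held HDAC5 alone. MEF2 factors with class IIa deacetylase partners and targets (14 members, 0.871) held none. Nor did nuclear oxidative phosphorylation (43 members, 0.28), mitochondrially encoded (13, 0.191), BCL2 family (13, 0.193), lysosome and autophagy (28, 0.871) and antigen presentation genes (15, 0.848) with group alone. In the fit with the replicate 1 term, oxidative phosphorylation genes held 1 higher and 3 lower, BCL2 family genes 2 lower, lysosome genes 2 higher and 4 lower, antigen presentation genes 1 lower and mitotic genes 1 higher and 1 lower.

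**Figure D5:**
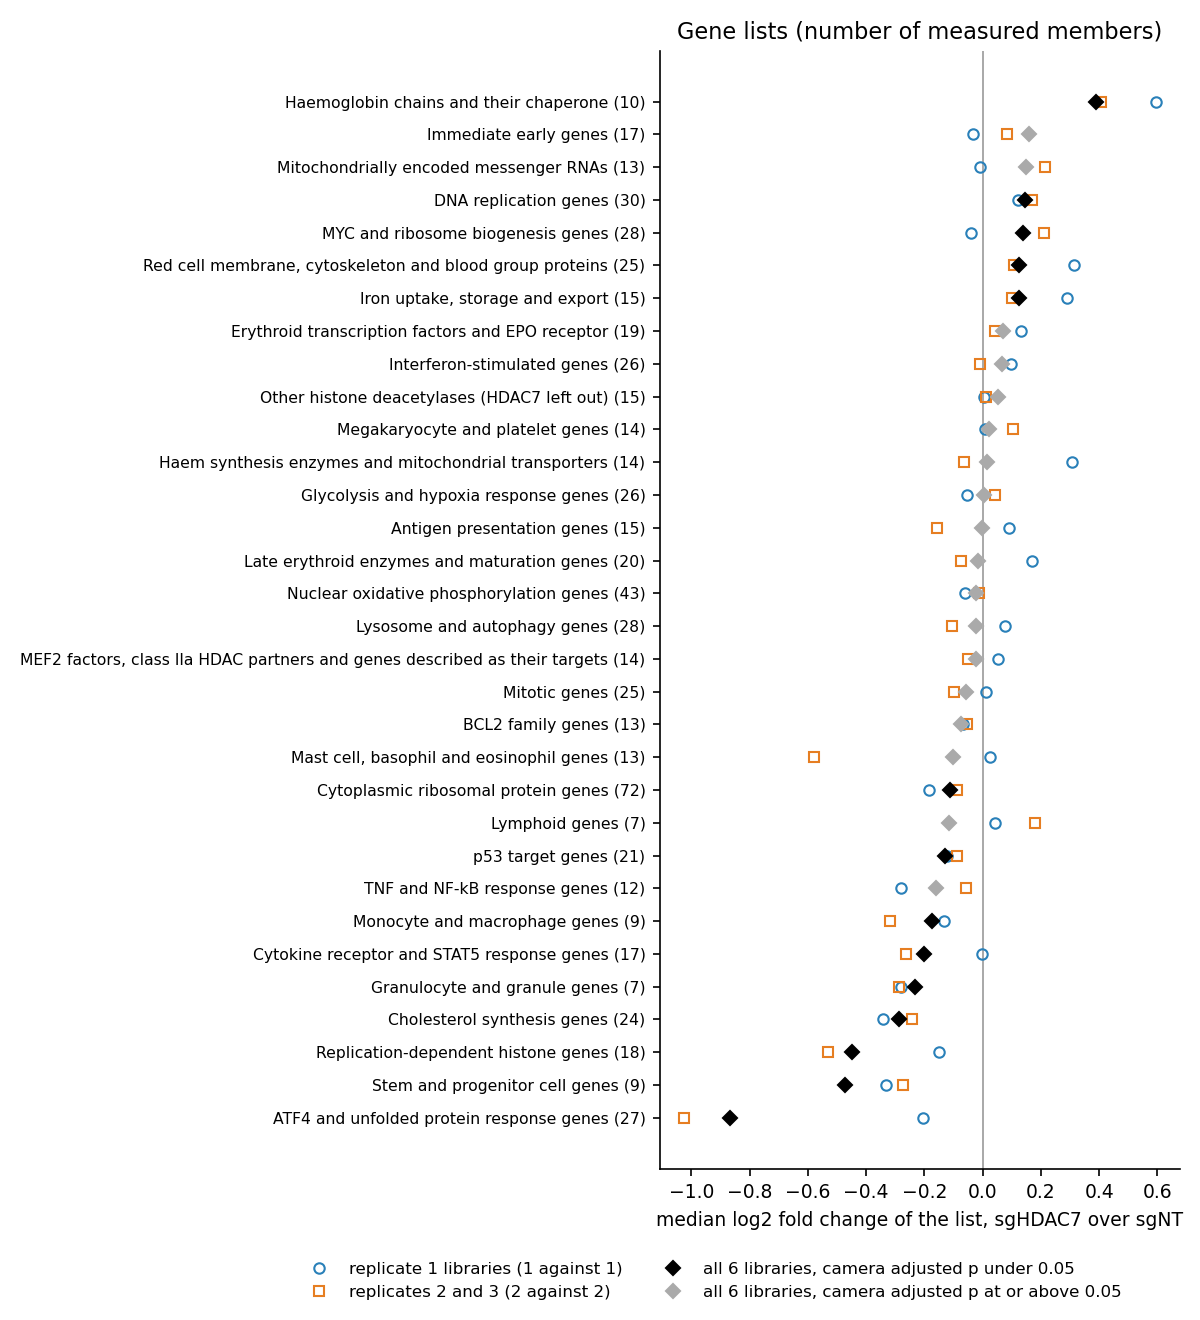
Median log2 fold change of sgHDAC7 over sgNT (horizontal) for the 32 gene lists (vertical, with the number of measured members), from all 6 libraries (diamonds, black where camera with the preset correlation called the list), from the replicate 1 libraries (circles) and from replicates 2 and 3 (squares). The ATF4 list lies at -0.87 over all libraries, -0.20 in replicate 1 and -1.03 in replicates 2 and 3, and the haemoglobin list lies at 0.39, 0.60 and 0.41.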

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

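The replicate 1 term and the fit on replicates 2 and 3 alone were chosen after seeing the data. The planned limma-trend test became an alternative once the file proved to hold counts. With group alone, edgeR called 396 genes, 161 higher, 235 lower and 79 changed at least 2-fold, and these kept their sign in every fit that tested them. Each fit reuses libraries on which the 396 were chosen, so the kept signs are no independent support. Limma without a trend called 55 (21 higher, 34 lower, 28 at least 2-fold). DESeq2 called 718 (294 and 424), 392 of them shared with the 396, and gave no adjusted p for 1342 genes. With the replicate 1 term the counts were 1743 (800 and 943, 165 at least 2-fold), and on replicates 2 and 3 they were 2847 (1345 and 1502, 236 at least 2-fold). Leaving out single libraries gave 27 to 1588 genes, 13 to 732 higher, 13 to 856 lower and 10 to 168 at least 2-fold. The cause was not tested, beyond the smaller groups. Limma-trend called 370, and filters, scalings, pseudocounts and the robust prior gave 334 to 425.

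Same-numbered libraries correlated in their deviations from the group means by 0.28, 0.09 and 0.08, so the numbers were not taken to pair the samples. Replicate 2 of each group correlated better with replicate 3 of the other (0.15 both ways). With a replicate block edgeR called 998 genes (430 higher, 568 lower), all 396 included, and camera 14 lists.

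Camera called 14 lists with the preset correlation, 0 with an estimated one, and fry 3. Other settings gave 12 to 17, and 11 of the 14 kept their call whichever library was left out. HDAC7 kept its direction and its call in all alternatives (log2 -1.08 to -0.92). Of 56 named genes called, 9 kept the call whichever library was left out, among them HDAC7, HDAC5, HBD, PLEK, EXOC3L4, IFITM1, IL1B and XBP1.

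Turns of sign were limited to results that did not pass the test with all 6 libraries. Among genes, HDAC11 had a log2 fold change of 0.0426 and GATA1 of -0.0401 on replicates 2 and 3 alone, GATA2 7e-04 without the filter on low values, and TFRC -0.0288 under quantile normalization. Leaving out single libraries gave -0.0332 to 0.16 for HDAC4, -0.66 to 0.15 for HDAC11, -0.0587 to 0.0931 for GATA1, -0.25 to 0.23 for GATA2, -1.19 to 0.25 for CD34 and -0.19 to 0.32 for HBG1.

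Camera's direction turned, with these adjusted p, for haem synthesis (0.981) and immediate early genes (0.506) on replicates 2 and 3 alone, and for late erythroid (0.971) and immediate early genes (0.842) with the replicate 1 term. In the fit with the replicate block these were 0.946 and 0.845. Lymphoid genes turned at a mean CPM of at least 5 (0.822), interferon (0.991) and glycolysis genes (0.979) without a trend, and mitochondrially encoded genes under quantile normalization (0.992). Adjusted p over the single-library omissions ran from 0.0407 to 0.915 for haem synthesis, 0.0561 to 0.586 for erythroid transcription factors, 0.0289 to 0.7 for late erythroid, 0.000766 to 0.915 for mast cell and 0.586 to 0.966 for lymphoid genes. They ran from 0.584 to 0.966 for MEF2 factors and partners, 0.32 to 0.947 for interferon, 0.48 to 0.966 for immediate early, 0.0082 to 0.37 for mitochondrially encoded and 0.533 to 0.948 for glycolysis genes. Lysosome and antigen presentation genes gave 0.266 to 0.915 and 0.464 to 0.966. The lowest adjusted p came without sgNT replicate 1 for late erythroid and mitochondrially encoded genes, without sgHDAC7 replicate 1 for mast cell genes and without sgNT replicate 3 for haem synthesis.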

Other observations

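The tests reported in this part were chosen after the pattern they address was seen, except the splits of the libraries without a replicate 1 term. The GC and length test and the muscle list were also chosen after their patterns were seen, but before their own outcomes were known.

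Replicate 1 differed from replicates 2 and 3 in 970 genes (edgeR with a group term, 461 higher and 509 lower in replicate 1). This fit gives 1 difference over both groups together, so a call need not hold in each group. HPGD differed by log2 1.00 in sgHDAC7 and 0.92 in sgNT, but INHBE by -0.36 and -3.54. The ATF4 list had medians of 0.03 in sgHDAC7 and -0.72 in sgNT. The genes named here were chosen after their values were seen. Camera with the preset correlation called all 6 erythroid lists lower in replicate 1, though none with an estimated correlation. The median log2 difference was -0.64 in sgHDAC7 and -0.76 in sgNT for haemoglobin genes (camera adjusted p = 1.22e-08; adjusted p = 0.229 with an estimated correlation) and -0.28 and -0.44 for red cell membrane genes. It was smaller for erythroid transcription factors (-0.06 and -0.26) and iron genes (0.00 and -0.14). SLC4A1, the band 3 anion exchanger, fell by 2.03 on the log2 scale (edgeR adjusted p = 6.8e-06). The mast cell list was higher in replicate 1, by a median of 1.01 in sgHDAC7 but 0.28 in sgNT (camera adjusted p = 4.92e-09; adjusted p = 0.229 with an estimated correlation), with CPA3, a mast cell protease, higher by log2 1.09 ± 0.07. Stem and progenitor genes had medians of 0.10 and 0.06 (camera adjusted p = 0.0382; adjusted p = 0.238 with an estimated correlation). CD34 was higher by log2 1.56 ± 0.13 and GATA2 by 0.62 ± 0.05. The immediate early gene FOS stood at 0.483 and 0.296 CPM in the 2 replicate 1 libraries and at 3.52 to 15.5 CPM in the other 4.

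Heat shock genes and muscle genes were followed up because HSPA1A, HSPA1B and MYO18B were among the largest rises. A heat shock list without HSPA1A and HSPA1B was higher in sgHDAC7 (19 members, camera p = 0.000353, but p = 0.306 with an estimated correlation), so whether the class rose stays open. With those 2 genes included (21 members), the median log2 ratio was -0.0027 between the replicate 1 libraries and 0.29 between replicates 2 and 3. HSPA1A stood at 562 and 555 CPM in sgHDAC7 replicates 2 and 3 against 154 and 152 CPM in sgNT, and at 319 against 259 CPM in replicate 1. A striated muscle list written without the genes already seen was not called (28 members, camera adjusted p = 0.509 over the heat shock and muscle lists), and of its members only PDLIM5 passed the edgeR test, with a rise of log2 0.76.

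Replicate 1 apart from replicates 2 and 3 is the first pattern weighed. Library size was tested and argues against itself as the cause: the total of replicate 1 over the mean of replicates 2 and 3 was 0.93 in sgNT and 1.03 in sgHDAC7. GC content and gene length accounted for an R2 of 0.00334 of the shared difference, and the correlation between the 2 groups' deviations, across genes, was 0.32 with and without them. A culture or library batch is a candidate source that stays open, since the labels give no date, and no biological explanation was tested.

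The fall of the ATF4 list is the second. A state of sgNT replicates 2 and 3 alone would leave no difference between the replicate 1 libraries, and their median log2 ratio was -0.20, with 22 of 27 members below 0 (-0.10 to 0.10 in the central 95% of 10000 random lists matched on expression). An equal fall in every replicate pair would leave no interaction with replicate 1, and camera gave p = 2.38e-26 for it (p = 0.00859 with an estimated correlation), with 20 members past the edgeR threshold. Adjusted over the 32 lists these were 7.61e-25 and 0.268. Both tests rest on 1 replicate 1 library per group. The random lists hold no variation between cultures, and the spread of the interaction comes from replicates 2 and 3 alone, so neither explanation is excluded. A stress state of sgNT replicates 2 and 3 may account for some or all of the fall, and an effect of the HDAC7 guide stays open beside it.

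The rise of HDAC5 beside the fall of HDAC7 is the third. A constant share of HDAC7 reads counted as HDAC5 would lower HDAC5, which instead changed by log2 2.13. That value is the pattern itself, so it speaks only against this form of sharing, and a changed assignment of reads was not tested. A change of its whole neighbourhood would raise the genes around it, but the 14 measured genes within 250 kb had a median log2 fold change of 0.10 with a standard error of the mean of 0.05. Their values ran from -0.15 (TMUB2) to 0.39 (MPP2). Among them UBTF was called (log2 0.30, edgeR adjusted p = 0.0455), and G6PC3 had log2 0.31 (adjusted p = 0.0936). The rise of HDAC5 may follow a reduced level of HDAC7, or come from the guide in another way, and neither was tested. MEF2 factors and partners as a list did not pass.

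The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave the most called genes, 396 against at most 0 (1 of 10 splits as large). Every other split mixes the guides, so the difference between the guides adds to the spread within its groups and holds down its gene calls. These low counts therefore do not show what a split without any guide difference would give. For lists, 3 of 10 splits gave at least the 14 of the real one, with 15 as the highest, in 2 splits that put both replicate 1 libraries on the same side. With the replicate 1 term the real split gave 14 lists, and the 5 other splits that part the replicate 1 libraries gave 6 to 11. In genes, edgeR with that term called 1743 in the real split and at most 2 in those 5, which mix the guides too and have the same limit.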
